A study of Mus musculus with 3 samples.

How the data were processed

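RNA of MGE-derived mouse neurons in culture was measured in 3 libraries, 1 each after 0, 1 and 6 h in 55 mM KCl, and the labels give no second library for any time. Per the labels' protocols, total RNA was extracted with Trizol, depleted of ribosomal RNA by RiboMinus treatment, fragmented, ligated in a directional way and sequenced on an ABi SOLiD instrument after PCR. The genome build named in the submitters' processing notes is mm9. Per the deposited counting logs, reads of 35 bp were kept if they mapped uniquely with at most 3 mismatches to the mouse genome of strain C57BL-6J or to a splice library of RefSeq exon pairs, and repeated reads at 1 position were kept. The aligner is not given in the sources used here.

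The authors' deposited counts are whole numbers of reads per gene, separated into sense and antisense strands and into exons, introns and the 500 bp on either side of the gene. The main values were the sense exonic read counts, raw and not normalised by the authors. Per the counting logs, the authors also gave a coverage signal per gene, the read bases per base scaled to 10000000 uniquely mapped reads, with a correction of the exonic value for the mappable part of the gene. That coverage was used as an alternative only. Because reads that map to several places were dropped, genes with near-identical copies are undercounted and their levels are uncertain. Sense and antisense reads were counted apart, so overlaps on opposite strands keep their reads separate, while genes that overlap on the same strand share reads. Of the 25562 genes, 1534 overlap another on the same strand and 3927 on either strand, and coordinates are those of the files, on mm9.

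Mapped reads stood at 2.45, 2.60 and 2.33 reads per distinct position at 0, 1 and 6 h. Antisense reads were 1.55%, 1.36% and 1.29% of exonic reads on both strands. The counting logs place the 3 libraries in 1 sequencing run, so no sequencing batch separates them. The 10 genes with most reads held 4.12%, 4.17% and 4.00% of exonic reads.

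Exonic counts were scaled with TMM factors of edgeR 4.0.16 in R 4.3.3. Each pair of libraries was compared by the ratio of scaled counts, with an exact Clopper-Pearson 95% interval computed from the split of the gene's reads between the 2 libraries (scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15). A gene counted as at least 2-fold higher or lower when its ratio was at least 2 or at most 0.5, the interval excluded 1, and 1 of the 2 libraries had at least 20 exonic reads. With 1 library per time no test between times, no replicate comparison and no leave-one-out could be run. A ratio against a library with 0 reads is given as a bound against 3 reads. Log2 ratios used a pseudocount of 0.5 reads. In 20 simulated data sets over all 25562 genes, 200 genes were changed, all picked from those with at least 20 exonic reads in 1 of the 2 libraries. Of genes changed 4-fold the rule called 99.8%, 99.9% and 99.8% in the comparisons of 1 h with 0 h, 6 h with 0 h and 6 h with 1 h. Of genes changed 2.5-fold it called 92.6%, 91.1% and 91.5%. These shares cover counting error only and do not hold for genes under the read minimum. Counts expected with no change came from 100 simulated draws in which every gene kept the same level. These draws held counting error of independent reads only, so they leave out variation between cultures and any effect of PCR copies.

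Before the data were examined, 13 gene lists and 8 marker lists were fixed. The gene lists were early transcription factors, early effectors and feedback regulators, late secreted and synaptic effectors, neuropeptides and hormones, GABA synthesis, transport and receptors, glutamate receptors and postsynaptic scaffolds, voltage-gated potassium channels, voltage-gated sodium and calcium channels, circadian clock, sterol synthesis and uptake, heat shock and unfolded protein response, glycolysis, and housekeeping reference genes. Marker lists covered MGE-derived interneurons, striatal and cholinergic neurons, excitatory cortical neurons, astrocytes and radial glia, the oligodendrocyte lineage, microglia, endothelial, mural and meningeal cells, and dividing cells. Members were matched by the symbol in the files or, for 22 entries, by gene identifier through a GRCm38 gene table used for names only, which held 22521 of the 25562 identifiers; 2 of 463 entries were not analysed here because they matched no gene in the files. Where the file's symbol is an older one, the current symbol follows in brackets. A list's median log2 ratio covers members with at least 20 exonic reads in at least 1 library. Its interval comes from 1000 Poisson redraws of the counts and so covers counting error only. Its percentile is among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries.

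The text names, for 1 h and 6 h against 0 h, the 15 genes higher and the 10 lower whose counting bound nearest to 1 lay farthest from 1, and the 5 and 5 for 6 h against 1 h. It also names up to 4 members per list, those with the largest and smallest log2 ratio at each time, and Npas4, Fos, Bdnf, Gad1, Gad2, Lhx6, Sst and Slc17a7. This rule took 106 genes, some of which are not reported here, nor are sums of marker lists that rest on them. Alternatives tried were scaling by total exonic reads, DESeq2 1.42.0 median-of-ratios size factors, the authors' coverage, no read minimum, a minimum of 50 reads, 1.5-fold and 3-fold rules, a 99% interval, exonic with intronic reads, intronic reads only, genes that overlap no other, and for lists a pseudocount of 5. In the alternative of intronic reads only, the libraries were scaled by TMM factors of the intronic reads. Matching random lists on intron length as well, and scaling exonic counts to all mapped reads, were added after seeing the data. Figures were drawn with matplotlib 3.10.9.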

Results

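Neurons from the medial ganglionic eminence (MGE), the embryonic brain region that gives rise to many cortical inhibitory interneurons, were taken from mouse embryos of the C57Bl/6 background at embryonic day 14 and grown for 10 days. On day 9 the cultures were silenced overnight with tetrodotoxin, a sodium channel blocker, and AP-5, an NMDA receptor antagonist. They were then depolarized by raising extracellular KCl to 55 mM for 0, 1 or 6 h. Ribosome-depleted total RNA was sequenced with its strand kept, in 1 library for each of the 3 times, to find the genes induced by activity in inhibitory neurons. The libraries held 8996897, 8549377 and 8579378 uniquely mapped reads at 0, 1 and 6 h. Sense exonic reads numbered 2189394, 2457167 and 2480579, which was 24.3%, 28.7% and 28.9% of the mapped reads. Of 25562 genes, 10311 had at least 20 exonic reads in at least 1 library. With 1 library per time no spread between cultures and no p-value can be given, so every ratio compares these libraries only. The 95% intervals are exact counting intervals that treat each read as independent and leave out variation between cultures. Repeated reads were kept and PCR copies were not marked by molecular identifiers, so the intervals may be too narrow even for counting error. A floor of 3 reads corresponded to 1.37, 1.22 and 1.21 reads per 1000000 exonic reads (RPM) at 0, 1 and 6 h.

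The cultures expressed genes of MGE-derived interneurons at every time. Of the 23 markers of this class in the files, 21 were measured, and together they held 9749.6, 9471 and 11391 scaled exonic RPM at 0, 1 and 6 h. Of the genes that encode the enzymes of GABA synthesis, Gad1 had 2787, 3457 and 5361 exonic reads and Gad2 had 2140, 1924 and 3159. Lhx6, a transcription factor of MGE-derived cells, had 838, 645 and 496 reads, and the neuropeptide gene Sst had 1146, 1414 and 1841. Slc17a7, which encodes a vesicular glutamate transporter, had 0, 1 and 0 reads, at or below the floor in each library. The 3 measured of 15 excitatory cortical markers were Cutl2 (Cux2), Camk2a and Emx2, and the whole list held 379, 321 and 320.3 RPM. Markers of astrocytes and radial glia formed the second largest class, with 15 of 16 measured and 3012, 3126 and 3647 RPM. The oligodendrocyte lineage (7 of 14 measured) held 175, 184 and 206 and dividing cells (11 of 16) 231, 234 and 203. Markers of endothelial, mural and meningeal cells (1 of 16, Pdgfrb) held 18.7, 18.3 and 18.1.

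The first comparison asked which RNAs differed after 1 h of depolarization. The largest differences were in immediate early genes, most of them transcription factors. Fos (chromosome 12, 86814851 to 86818219, mm9), a subunit of the AP-1 transcription factor, had 21, 2901 and 877 reads at 0, 1 and 6 h and was 123-fold (interval 80.4 to 199) higher at 1 h. Nr4a1 (chromosome 15, 101097293 to 101105223), an orphan nuclear receptor, had 0, 367 and 72 reads and was at least 109-fold higher against the floor. Npas4 (chromosome 19, 4984355 to 4989971), a neuronal activity-dependent transcription factor, had 9, 802 and 163 reads and was 79.5-fold (interval 41.7 to 174) higher. Fosb was 170.3-fold (interval 58.0 to 828) higher, Egr2 105-fold (interval 35.5 to 509.9) and Junb 49.8-fold (interval 28.9 to 94.0).

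The rest of the 15 highest-ranked genes at 1 h included Arc, a regulator of AMPA receptor endocytosis, at 19.7-fold (interval 13.4 to 30.1), and Egr1 at 15.2-fold (interval 12.3 to 19.0). Nr4a3 was 22.8-fold higher (9.53 to 71.5) and Egr3 18.7-fold higher (6.12 to 93.2). Maff, with 1 read at 0 h, was 63.3-fold higher (11.0 to 2536). The phosphatase genes Dusp1 and Dusp6, whose products inactivate MAP kinases, were 8.81-fold (6.72 to 11.8) and 9.33-fold (6.23 to 14.5) higher. The secreted neuropeptide precursor Vgf, with 3 reads at 0 h, was 21.7-fold higher (7.14 to 108). LOC668604, a predicted gene of 2 exons (chromosome 11, 74985977 to 74986583), had 1, 42 and 0 reads and was 37.5-fold higher (6.37 to 1514).

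The genes lower at 1 h differed by smaller factors. Ctnnb1 (chromosome 9, 120842593 to 120869625), which encodes beta-catenin, had 1148, 477 and 449 reads and was 2.70-fold (interval 2.42 to 3.01) lower. Hes5, a Notch target of neural progenitors and glia, was 3.83-fold (interval 1.98 to 8.01) lower. The translation factor gene Eif5b was 2.81-fold (2.02 to 3.97) lower and the ubiquitin ligase gene Smurf2 3.04-fold (1.99 to 4.75). The endothelin-converting enzyme gene Ece1 was 2.65-fold (1.87 to 3.81) lower and the atypical cadherin Celsr2 2.14-fold (1.83 to 2.51). 1810007P19Rik (Oscp1), Zc3h6, Lrrc56 and BC068157 (Prr36) completed the 10 lower genes, at 5.29-fold, 3.68-fold, 5.16-fold and 2.71-fold lower. Their intervals ran 2.30 to 14.2, 1.99 to 7.26, 1.92 to 17.4 and 1.97 to 3.78.

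By the size rule, 159 genes were at least 2-fold higher and 144 at least 2-fold lower at 1 h among 10093 compared. Simulated libraries with no change gave a mean of 26.8 higher and 22.6 lower genes from counting error. At least 5-fold differences were seen for 29 genes higher and 2 lower. Higher genes made up 52.5% of the calls, and 85.2% on the authors' normalised coverage, which is scaled to all mapped reads.

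**Figure D1:**
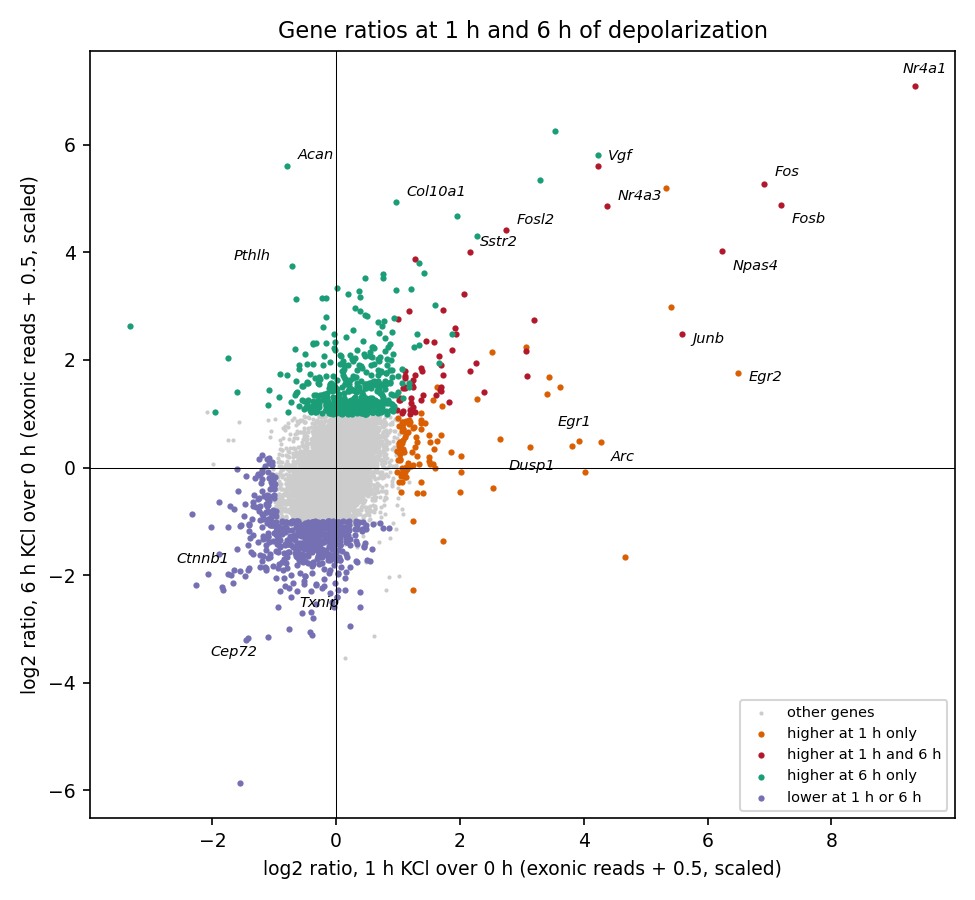
Each point is 1 of 10311 measured genes, with the log2 ratio of scaled exonic reads (0.5 reads added) of the 1 h over the 0 h library on the x axis and of the 6 h over the 0 h library on the y axis. Colours mark the 100 genes higher at 1 h only, the 59 higher at both times, the 438 higher at 6 h only and the genes lower at either time; Fos and Npas4 lie high on both axes, Egr1 and Arc on the x axis, and Acan on the y axis.

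The gene lists fixed before the data were examined differed in their response at 1 h. Of 26 measured early transcription factors, 22 were at least 2-fold higher, 0 lower and 4 neither. Their median log2 ratio was 3.24 (2.69 to 3.82), above all 10000 random lists matched on expression. The smallest member was Bhlhb2 (Bhlhe40) at 1.17-fold (interval 0.722 to 1.92). Of 33 early effectors and feedback regulators, 20 were higher and 13 neither, with a median of 1.21 (1.10 to 1.52), also above all random lists. Among them Dusp5 was at least 6.54-fold higher and the growth arrest gene Gadd45g 4.08-fold (interval 2.52 to 6.89), while Spred1 had a ratio of 0.914 (0.732 to 1.14). Of 24 late secreted and synaptic effectors, 2 were higher: Vgf and, named after its value was seen, the prohormone convertase gene Pcsk1 at 2.01-fold (interval 1.27 to 3.25). In this list the neurofilament gene Nefm was 2.06-fold (interval 1.24 to 3.50) lower and 21 were neither. Its median was 0.21 (0.12 to 0.45), at percentile 99.6, no higher than that of the housekeeping genes at 0.25 and percentile 99.9.

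Genes of sterol synthesis and uptake were higher as a group at 1 h: 5 of 17 were at least 2-fold higher, 12 were neither, and the median of 0.57 (0.43 to 0.71) lay above all random lists. They included, named after their values were seen, Sc4mol at 2.41-fold (interval 2.10 to 2.77), Insig1 at 2.18-fold (1.79 to 2.67) and Hsd17b7 at 2.11-fold (1.71 to 2.62). Pmvk had the lowest ratio, 0.777 (0.589 to 1.02), and Mvk the lowest at 6 h, 0.706 (0.490 to 1.01). In the heat shock and unfolded protein response list, 2 of 21 were higher: the cochaperone gene Dnajb1, at 3.23-fold (interval 2.60 to 4.04), and Atf4, at 2.34-fold (interval 2.08 to 2.64), named after its value was seen. The median of that list was 0.28 (0.18 to 0.45), above all random lists. The housekeeping genes had a similar median at 1 h, 0.25 (0.13 to 0.37), at percentile 99.9. A high percentile at a median this small therefore does not by itself mark a response. Of 15 circadian clock genes, Per2 was 3.32-fold (interval 1.68 to 7.17) higher and Per1 2.61-fold (2.07 to 3.30), and 13 were neither (median 0.05, interval -0.20 to 0.31, percentile 73.0); Hlf was lowest at 0.613 (0.339 to 1.09).

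Neurotransmission genes differed little at 1 h. None of 21 genes of GABA synthesis, transport and receptors met the rule (median 0.07, interval -0.02 to 0.14, percentile 74.2). Of 28 glutamate receptor and scaffold genes, Grik4 and Grm4 were lower, 2.24-fold (interval 1.08 to 4.92) and 2.05-fold (interval 1.20 to 3.57), and 26 were neither; Grik1 was highest at 1.20 (1.11 to 1.30). The list median was -0.12 (-0.22 to -0.03), at percentile 2.35. Of 24 voltage-gated potassium channels, Kcnv1 was 2.31-fold (interval 1.26 to 4.39) lower and 23 were neither (median -0.23, interval -0.35 to -0.06, percentile 0.400). None of 22 sodium and calcium channels met the rule, from Cacna1i at 0.519 (0.408 to 0.657) to Scn2b at 1.22; their median was -0.16 (-0.25 to -0.04), at percentile 0.890. When random lists were matched on intron length as well, a choice made after seeing the data, these 3 lists lay at percentiles 13.6, 0.680 and 6.04. None of 10 neuropeptide genes met the rule at 1 h (median 0.16, interval -0.13 to 0.43, percentile 88.7), and Chga had a ratio of 0.791 (0.665 to 0.941). None of 17 glycolysis genes (median 0.22, interval 0.07 to 0.29, percentile 99.6) or of 16 housekeeping genes (median 0.25, interval 0.13 to 0.37, percentile 99.9) did. In glycolysis Slc2a1 was highest at 1.71 (1.19 to 2.48) and Hk1 lowest at 0.853 (0.742 to 0.981), and among housekeeping genes Polr2a was lowest at 0.788 (0.672 to 0.922).

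Among marker genes, the MGE factor Lhx8 was 2.39-fold (interval 1.53 to 3.83) higher and Emx2, a cortical progenitor factor, 2.56-fold (interval 1.11 to 6.63), while Hes5 was lower. In the other marker lists no gene met the rule at 1 h. The list medians were -0.02 (-0.10 to 0.06) for MGE-derived interneurons, -0.12 (-0.26 to 0.04) for astrocytes and radial glia, 0.21 (-0.21 to 0.41) for the oligodendrocyte lineage and 0.04 (-0.28 to 0.32) for dividing cells. All 4 lay between percentiles 6.75 and 89.6. Excitatory markers had a median of -0.16 (-0.32 to 0.00) over 3 genes, with Camk2a at 0.640 (0.515 to 0.793).

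The second comparison set 6 h against 0 h, the stage at which secondary response genes are measured. The leading gene was Acan (chromosome 7, 86198369 to 86259985), which encodes aggrecan, a proteoglycan of perineuronal nets: it had 8, 5 and 439 reads and was 51.9-fold (interval 26.1 to 121) higher at 6 h. Vgf was 56.4-fold (interval 19.0 to 276) higher and Fosl2, an AP-1 subunit, 21.5-fold (interval 16.1 to 29.5). Genes of secreted and matrix proteins were among the 15 highest-ranked: the collagen gene Col10a1 at 37.8-fold (interval 10.1 to 318), Ctgf (Ccn2) at 15.1-fold (interval 8.83 to 28.1) and the parathyroid hormone-like gene Pthlh at 13.9-fold (interval 7.74 to 27.4). The protease gene Prss23, with 0 reads at 0 h and 40 at 6 h, was at least 12.6-fold higher.

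Sstr2, a somatostatin receptor gene, was 17.2-fold (interval 8.09 to 43.5) higher at 6 h. Rab39, which shares its strand with an overlapping gene model, was at least 9.14-fold higher. Several genes that led at 1 h remained among the 15: Fos at 39.5-fold (25.7 to 64.1), Fosb at 34.4-fold (11.5 to 169), Npas4 at 17.1-fold (8.80 to 38.1) and Nr4a3 at 31.8-fold (13.3 to 99.1). Nr4a1 was at least 22.7-fold higher.

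Among genes lower at 6 h, B930008K04Rik (Zmat1) had 27, 10 and 0 reads and was at least 9.52-fold lower. Slc16a6, a monocarboxylate transporter family gene, was 9.52-fold (interval 4.36 to 24.6) lower, and Txnip, an inhibitor of thioredoxin, 4.76-fold (interval 3.33 to 6.95). Dclre1c, which encodes the nuclease Artemis, was 9.09-fold (interval 3.61 to 29.4) lower, and Mtmr15 (Fan1), a nuclease gene that shares its strand with an overlapping gene model, 6.87-fold (interval 2.89 to 19.9). The receptor phosphatase gene Ptpru was 4.09-fold (2.86 to 5.98) lower and the adaptor gene Ap4b1 4.65-fold (2.99 to 7.50). Cecr6 (Tmem121b) was 5.02-fold (2.90 to 9.23) lower. Cep72 and Zfp786 both had 3 reads at 6 h, and were 10.2-fold (3.17 to 52.4) and 10.6-fold (3.29 to 54.1) lower.

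In all, 497 genes were at least 2-fold higher and 547 at least 2-fold lower at 6 h among 10095 compared, against means of 24.4 and 24.6 in simulated unchanged libraries. At least 5-fold differences were seen for 70 genes higher and 28 lower. Higher genes made up 47.6% of the calls, 35.6% when libraries were scaled by total exonic reads and 64.1% on the authors' normalised coverage.

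**Figure D2:**
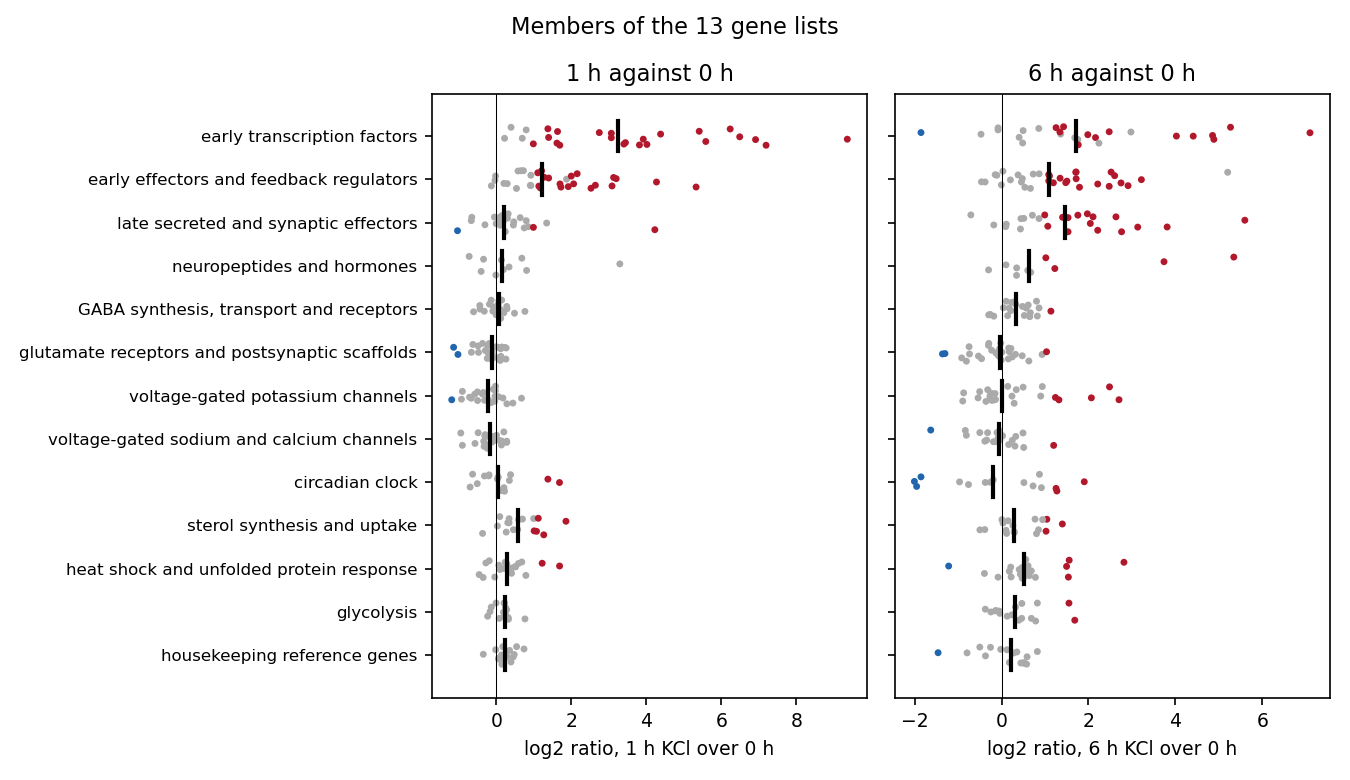
Each point is a measured member of 1 of the 13 gene lists, placed by its log2 ratio of scaled exonic reads (0.5 reads added) at 1 h (left) or 6 h (right) over 0 h; red points met the 2-fold rule as higher, blue as lower, grey neither, and the black bar is the list median. Early transcription factors have a median of 3.24 at 1 h and 1.72 at 6 h, and late secreted and synaptic effectors 0.21 and 1.47.

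The late secreted and synaptic effectors were higher at 6 h: 15 of 24 were at least 2-fold higher, 0 lower and 9 neither, with a median log2 ratio of 1.47 (1.20 to 1.57), above all random lists. Besides Vgf these included, named after their values were seen, Pcsk1 at 6.89-fold (interval 4.63 to 10.6), the neuronal pentraxin gene Nptx2 at 6.29-fold (interval 4.24 to 9.65) and the growth factor gene Igf1 at 4.14-fold (interval 3.17 to 5.48). Lingo1 had the lowest ratio, 0.612 (0.476 to 0.784), and Nefm stood at 1.07 (0.705 to 1.63). Bdnf had 0, 0 and 3 exonic reads, at or below the floor in each library, so a difference in it was not detectable at this depth. Early transcription factors had 13 of 26 higher, 1 lower and 12 neither, with a median of 1.72 (1.35 to 2.10). The lower gene was Bhlhb2, by 3.76-fold (interval 1.75 to 8.96). Early effectors and feedback regulators had 18 of 33 higher and 15 neither, with a median of 1.10 (0.98 to 1.37); Gadd45g stood at 0.721 (0.352 to 1.45). Both medians lay above all random lists.

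Neuropeptide and hormone genes had 4 of 10 higher and 6 neither at 6 h, with a median of 0.64 (0.44 to 0.99), at percentile 99.8. The 4 were Pthlh, Cartpt at 0, 5 and 21 reads and at least 6.62-fold higher, and, named after their values were seen, Nppc at 2.42-fold (1.08 to 5.93) and Penk1 (Penk) at 2.06-fold (1.13 to 3.90). Chga stood at 0.812 (0.681 to 0.967). In the GABA list, Gabra2, a GABA-A receptor subunit gene, was 2.20-fold (interval 1.89 to 2.56) higher and 20 were neither; the median was 0.33 (0.23 to 0.48), at percentile 99.3, and Gabbr2 was lowest at 0.814 (0.688 to 0.962). Of the glutamate receptor and scaffold genes, Dlg1 was 2.05-fold (interval 1.64 to 2.58) higher, Grm4 and Grik4 were 2.61-fold (1.46 to 4.90) and 2.54-fold (1.17 to 5.95) lower, and 25 were neither (median -0.05, interval -0.16 to 0.03, percentile 11.6).

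Ion channel genes differed in direction at 6 h. Kcnf1, a modulatory potassium channel subunit gene, was 6.59-fold (interval 4.61 to 9.68) higher, and 4 more of the 24 potassium channels, named after their values were seen, met the rule: Kcns2 at 5.64-fold (4.23 to 7.65), Kcna4 at 4.23-fold (2.99 to 6.12), Kcnq3 at 2.54-fold (1.47 to 4.55) and Kcna1 at 2.37-fold (1.87 to 3.02). The other 19 were neither, with Kcnd1 at 0.532 (0.281 to 0.977), and the median was 0.00 (-0.10 to 0.21), at percentile 54.6. Scn1a, a sodium channel gene that shares its strand with an overlapping gene model, was 2.30-fold (interval 2.03 to 2.61) higher. Cacna1d, an L-type calcium channel gene, was 3.11-fold (interval 2.36 to 4.15) lower, and 20 of 22 sodium and calcium channels were neither (median -0.06, interval -0.17 to 0.02, percentile 11.2).

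Of the remaining lists at 6 h, the circadian clock had 3 of 15 higher, 3 lower and 9 neither, with a median of -0.19 (-0.35 to 0.44) at percentile 24.0. Per2 was 3.87-fold (interval 1.97 to 8.29) higher, as were Per1 and Rorb, and Per3 was 4.14-fold (interval 2.16 to 8.58) lower, as were Bhlhb2 and Dbp; Per1, Rorb and Dbp were named after their values were seen. The heat shock and unfolded protein response list had 4 of 21 higher, 1 lower and 16 neither, with a median of 0.51 (0.38 to 0.65), above all random lists. Its higher members were Chac1, a glutathione-degrading enzyme gene, at 7.13-fold (interval 5.00 to 10.5), and, named after their values were seen, Asns, Herpud1 and Atf4, from 2.82-fold to 2.95-fold; Creld2 was 2.36-fold (interval 1.30 to 4.47) lower. Sterol genes had 3 of 17 higher and 14 neither (median 0.29, interval 0.18 to 0.53, percentile 96.7), among them Cyp51 at 2.64-fold (interval 2.40 to 2.91). Glycolysis had 2 of 17 higher and 15 neither (median 0.32, interval 0.12 to 0.44, percentile 98.3). They were Hk2, which shares its strand with an overlapping gene model, at 3.38-fold (interval 1.42 to 9.25), and Slc2a3, named after its value was seen, at 2.93-fold (2.65 to 3.25); Eno2 was lowest at 0.771 (0.657 to 0.905). Of 16 housekeeping genes, Polr2a, which encodes the largest subunit of RNA polymerase II, was 2.76-fold (interval 2.25 to 3.40) lower and 15 were neither (median 0.23, interval 0.10 to 0.33, percentile 92.9), with Pgk1 highest at 1.79 (1.00 to 3.31).

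Marker genes of the interneuron class did not meet the rule at 6 h in any of the 21 measured, with a median of 0.09 (-0.09 to 0.14). Gad1, which shares its strand with an overlapping gene model, was 1.82-fold (interval 1.74 to 1.90) higher, Gad2 1.40-fold (1.32 to 1.48) and Sst 1.52-fold (1.41 to 1.64) higher, and Lhx6 had a ratio of 0.560, with an interval that ended at 0.626. At 1 h the ratios were 1.11 (1.05 to 1.16) for Gad1, 0.802 (0.754 to 0.853) for Gad2, 1.10 (1.02 to 1.19) for Sst and 0.686 (0.618 to 0.762) for Lhx6. Among glial markers Slco1c1 was 4.11-fold (interval 2.90 to 5.96) higher, Vim, named after its value was seen, 2.10-fold (1.91 to 2.30), and Olig2 2.04-fold (interval 1.45 to 2.92). Hes5 was 3.10-fold (interval 1.65 to 6.15) lower and Pdgfra 2.21-fold (interval 1.52 to 3.26). In the striatal list Foxp1 stood at 0.516 (0.319 to 0.819). Of the dividing cell markers, Cdc2a (Cdk1) was 2.14-fold (interval 1.34 to 3.50) higher and Rrm2 2.43-fold (interval 1.11 to 5.72) lower. Medians at 6 h were 0.05 (-0.11 to 0.13) for astrocytes and radial glia, 0.01 (-0.33 to 0.65) for the oligodendrocyte lineage, -0.30 (-0.58 to 0.00) for dividing cells and -0.19 (-0.40 to -0.02) for excitatory neurons.

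The third comparison, of 6 h with 1 h, separated transient from late responses. Higher at 6 h were Acan, at 93.1-fold (interval 39.6 to 288), Pthlh, at 23.3-fold (interval 11.6 to 54.9), Col10a1, at 17.0-fold (interval 6.98 to 53.7), and Cacng5, an auxiliary AMPA receptor and calcium channel subunit gene, at 10.6-fold (interval 6.80 to 17.2). Tagln, an actin-binding protein gene of smooth muscle, had 4, 0 and 29 reads and was at least 10.3-fold higher at 6 h than at 1 h. Lower at 6 h were Egr2, at 27.7-fold (interval 15.6 to 54.1), Arc, with 27, 595 and 40 reads at 0, 1 and 6 h and a ratio of 0.0713 (0.0504 to 0.0982), Egr1, at 10.8-fold (interval 9.00 to 12.9), and Junb, at 8.67-fold (interval 6.86 to 11.1). LOC668604 was at least 13.2-fold lower. By the size rule 423 genes were higher and 469 lower among 10137 compared, against means of 23.4 and 24.3 in simulated unchanged libraries. Higher genes made up 47.4% of the calls, 35.4% on total exonic reads and 36.4% on the authors' normalised coverage.

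**Figure D3:**
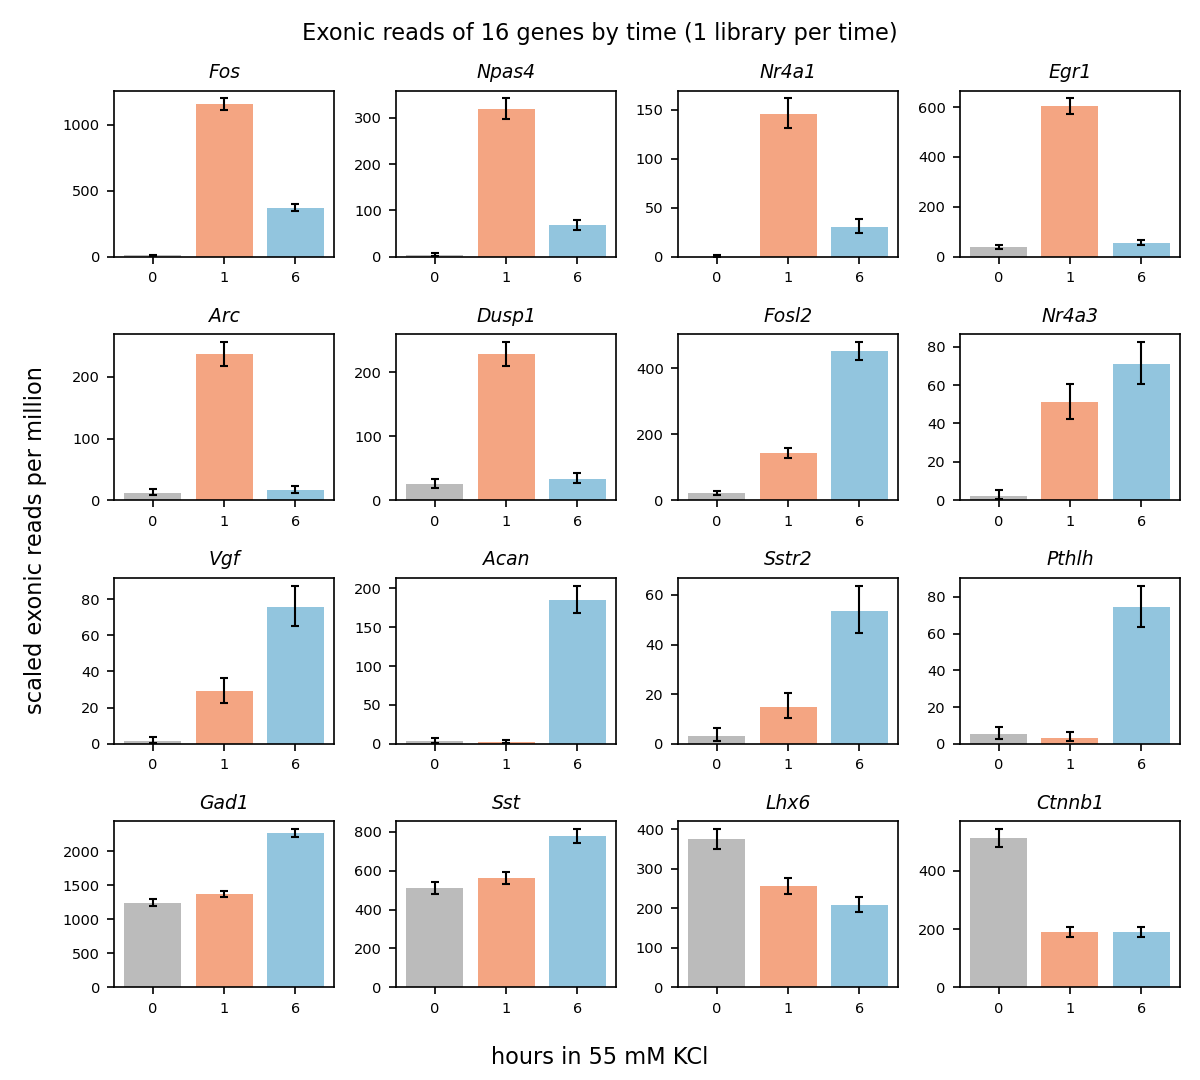
Bars give the scaled exonic RPM of 16 genes (y axis, linear and from 0, scaled per gene) in the single libraries at 0, 1 and 6 h in KCl (x axis), and error bars are exact 95% Poisson intervals, which cover counting error only. Egr1 and Arc are highest at 1 h, Acan and Pthlh at 6 h, and Ctnnb1 is highest at 0 h.

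The genes at least 2-fold higher fell into 3 time classes: 100 at 1 h only, 59 at both times and 438 at 6 h only. Of the genes higher at 1 h only, 48 were also at least 2-fold lower at 6 h than at 1 h, while 277 of the 438 late genes were at least 2-fold higher at 6 h than at 1 h. Among early-only genes, 49 had under 20 reads in both the 0 h and the 6 h library, and 108 late-only genes had under 20 reads in both the 0 h and the 1 h library. Among 9877 genes compared at both times, 110 were higher at 1 h and 389 at 6 h, and 59 were shared. Independent lists of these sizes would share 4.33 genes, and simulated unchanged libraries that share the 0 h library gave a mean of 4.57 and at most 11. In the lower direction 64 genes were shared by 144 at 1 h and 547 at 6 h, where independent lists would share 7.97 and the simulation gave a mean of 2.79. With 1 control library, part of each excess may come from that shared library. No gene met the rule in opposite directions at the 2 times.

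Reads from introns, which come mainly from unspliced RNA, were lower at 1 h. Sense intronic reads numbered 2123187, 1789710 and 2095060. On the exonic scaling the median log2 ratio of intronic reads over 8368 genes was -0.65 at 1 h (quartiles -1.03 and -0.20) and -0.19 at 6 h (-0.57 and 0.17). The 1 h value moved with intron length, from 0.21 in the 181 genes with the shortest introns in total to -0.83 in 1283 genes with 100 to 316 kb of intron, and was -0.76 in the 380 genes with the longest. The median exonic log2 ratio at 1 h was lower in each longer class, from 0.18 in the shortest to -0.14 in the longest. Against this background the introns of Gad1 held 729, 1642 and 1524 reads, 2.01-fold higher at 1 h (1.84 to 2.19). Gad1 shares its strand with an overlapping gene model, so some of these reads may belong to that model. The introns of Ctnnb1 had a ratio of 0.910 (0.742 to 1.12).

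**Figure D4:**
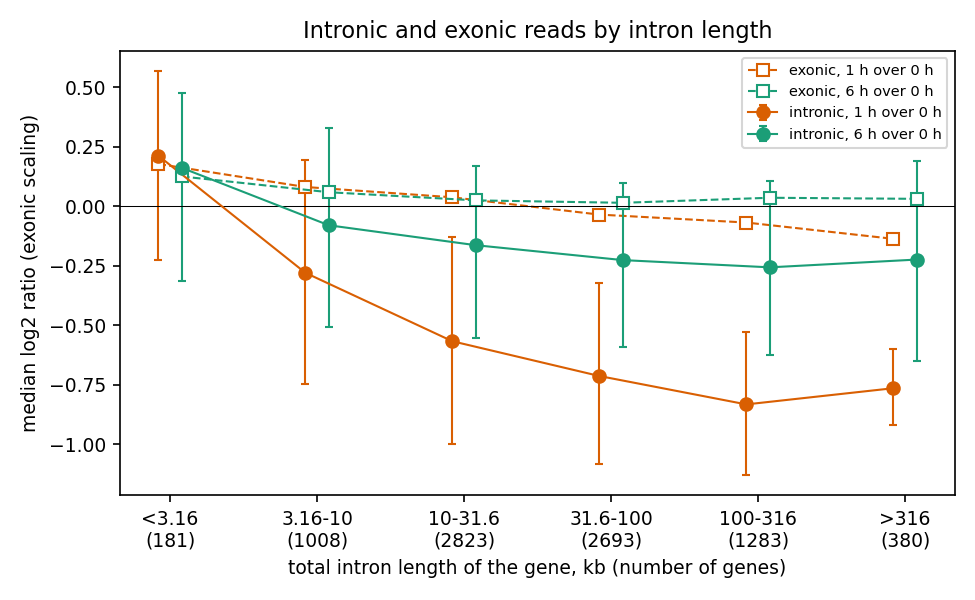
Median log2 ratio over 0 h, on the exonic scaling, of intronic reads (filled circles, bars from the lower to the upper quartile) and exonic reads (open squares) at 1 h and 6 h (y axis), for genes binned by total intron length in kb (x axis, with the number of genes). The intronic median at 1 h goes from 0.21 in the shortest class to -0.83 in the 100 to 316 kb class and is -0.76 in the longest.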

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

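The tests of scaling by exonic reads, of a change in unspliced RNA and of the Ctnnb1 pattern were chosen after their results were seen; those on antisense reads and on nuclear RNAs were written before.

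Gad2 is listed because its counting intervals at 1 h and 6 h lay on opposite sides of no change, and the difference between the times was not tested beyond counting error. Gad2 had a log2 ratio of -0.32 at 1 h and 0.48 at 6 h. Scaling to all mapped reads moves every log2 ratio at 1 h up by 0.24, after which the Gad2 interval at 1 h includes no change.

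Signals outside the sense exonic counts were not part of the comparisons, and their differences from 0 h were not tested beyond counting error. Antisense exonic reads were at least 2-fold higher in 10 genes at 1 h and 21 at 6 h. No count expected with no change is given here. Some of these genes overlap a gene on the opposite strand, as Ctsb does Fdft1 and Gm166 does Phkg2. Their antisense reads can be sense reads of the other gene. The exons of Ovca2 (chromosome 11, 74989445 to 74992310, mm9) led at 1 h, with 4, 185 and 21 antisense reads, a ratio of 41.2 (15.8 to 153). LOC668604 is its neighbour on that strand, and a GRCm38 gene table lists Mir212 and Mir132 between Hic1 and Ovca2. Sense reads in the 500 bp downstream of genes were at least 2-fold higher in 30 genes at 1 h and 99 at 6 h. They included Nr4a3, with 0, 26 and 52 reads.

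Lower intronic reads at 1 h were the widest shift in these libraries: 82.6% of 8368 genes had a lower ratio. Genomic DNA in the 0 h library would add reads to both strands, but the loss of antisense intronic reads was 8.80% of the loss of sense reads. Scaling by exonic reads is not the whole reason, since the median log2 ratio stayed at -0.42 when libraries were scaled by all mapped reads. A lower yield of nuclear RNA at 1 h is argued against as the whole source, and a smaller loss stays open. Of 14 nuclear noncoding RNAs listed, 8 were measured. Their median log2 ratio was -0.23 and their lower quartile -0.33, between no change and the intronic shift of -0.65. They did not move together. Those with most reads besides Xist, picked after their values were seen, fell by less than the 1.57-fold of introns or rose. The ratios were 0.861 (0.811 to 0.914) for A930034L06Rik (Snhg11) and 0.885 (0.801 to 0.978) for Tug1. They were 0.941 (0.851 to 1.04) for Gtl2 (Meg3) and 1.18 (1.09 to 1.29) for Peg13. Xist went the other way, at 0.554, and was also lower at 6 h, which may reflect embryo sex. A change of unspliced RNA with depolarization cannot be told apart from a property of that library, because each time has 1 library; the median was -0.65.

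Lower Ctnnb1 reads, at both times, were weighed because the gene ranked first among those lower at 1 h. A pile of reads on 1 exon of the 0 h library is argued against: without the exon with most reads the ratio was 0.378 (0.322 to 0.441), and all 13 exons with at least 10 reads at 0 h were lower at 1 h by a ratio of 0.75 or less. A lower RNA level with little change in unspliced RNA may account for it, since the intronic ratio on the exonic scaling was 0.910 (0.742 to 1.12). On the scaling by intronic reads the log2 intronic ratio was 0.47, so little change in unspliced RNA depends on the scaling. A lower RNA level cannot be told apart from a difference between 2 single cultures.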

How the results depend on the processing

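The alternatives below were planned, except the matching of random lists on intron length and the scaling of exonic counts to all mapped reads, which were chosen after the data were seen. No paired analysis was possible because each time has 1 library. For 1 h against 0 h, DESeq2 size factors, total exonic reads, the 99% interval and the removal of overlapping genes kept both counts within 1.5 times; for 6 h against 0 h and 6 h against 1 h, so did every alternative but the read minimum of 50 and the other folds. Counts near the main ones did not always hold the same genes: on intronic reads 161 of the 497 higher and 80 of the 547 lower genes were shared at 6 h against 0 h, and 102 of 423 and 45 of 469 for 6 h against 1 h. On exonic with intronic reads 365 and 307 were shared at 6 h against 0 h and 260 and 253 for 6 h against 1 h. At 1.5-fold the counts were 380 higher and 535 lower at 1 h, 1172 higher and 1334 lower at 6 h and 1002 higher and 1102 lower for 6 h against 1 h. At 3-fold they were 59 higher and 19 lower, 183 higher and 149 lower and 143 higher and 118 lower. A minimum of 50 reads left 82 higher and 51 lower at 1 h, 235 lower at 6 h and 229 lower for 6 h against 1 h. Without a minimum 257 were lower at 1 h. At 1 h the authors' normalised coverage gave 288 higher and 50 lower, and the exonic counts scaled to all mapped reads, as that coverage is, gave 296 higher and 52 lower. This scaling alone moved the log2 ratios of all genes by 0.24 at 1 h and 0.15 at 6 h. Exonic with intronic reads gave 265 higher and 291 lower at 1 h, of which 126 and 54 were shared with the main calls. Intronic reads alone, scaled by their own TMM factors, gave 609 higher and 504 lower, of which 47 and 15 were shared. On the exonic scaling intronic reads gave 211 higher and 2214 lower at 1 h. The same scaling gave 254 higher and 861 lower at 6 h, and 1200 higher and 205 lower for 6 h against 1 h. The cause of these differences from the exonic counts was not tested. Genes higher at 1 h only, both times and 6 h only were 214, 166 and 1006 at 1.5-fold and 36, 23 and 160 at 3-fold. With a minimum of 50 reads there were 48 early-only genes and 34 at both times. At 1 h, 7 of the 13 gene lists, the housekeeping genes among them, lay above the central 95% of random lists and 3 below. The latter were 0 on intronic reads and 1 with intron length matched. On intronic reads 1 list lay below at 6 h. With a pseudocount of 5 the median of early transcription factors was 2.42 at 1 h and 1.25 at 6 h, and that of early effectors and feedback regulators 1.08 at 1 h. Intronic reads gave early transcription factors 5.17 at 1 h, early effectors 2.35 and 0.72 at 1 and 6 h, and late effectors 0.93 and 0.97; for these and the list counts the cause was not tested. With no read minimum early and late effectors were 0.87 and 1.06 at 6 h. With no read minimum the medians of the circadian clock at 6 h (0.56, over 18 genes), of potassium channels at 6 h (-0.14, over 29) and of endothelial, mural and meningeal markers at 1 h (0.57, over 12) were among those that turned sign; the cause was not tested. Some medians turned sign on intronic reads scaled by their own TMM factors. They were those of striatal and cholinergic markers at 1 h (-0.68) and 6 h (-0.43, over 3 genes), of MGE-derived interneuron markers at 1 h (0.23) and of the circadian clock at 6 h (0.46). The cause was not tested. Among named genes that met the 2-fold rule, Cep72 (0.24) and Ctnnb1 (0.47) turned sign at 1 h. On the exonic scaling their intronic ratios were 0.770 (0.394 to 1.49) and 0.910 (0.742 to 1.12), with intervals on both sides of 1. These were already nearer to 1 than the exonic ratios of 0.461 and 0.371. The turn of sign therefore came with the intronic scaling, while part of the move came with the change to intronic reads. Of 222 ratios of named genes, those that kept their direction and their side of the rule were 221 with DESeq2 size factors, 217 with the 99% interval, 217 with no read minimum, 216 with total exonic reads, 203 on exonic with intronic reads, 194 at 1.5-fold, 193 at 3-fold and 183 with a minimum of 50 reads. On the authors' coverage 194 of 205 did, and on intronic reads 69 of 107. Depth limits low genes: with 0 reads at 0 h and 3 at 6 h, as for Bdnf, no ratio can be given.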

Other observations

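The test of overlapping genes was written before its result was seen, and the other tests and all genes named here were chosen afterwards. Introns of some late genes were higher at 1 h. Hsd17b12, an enzyme of fatty acid elongation, had 114, 876 and 475 intronic reads at 0, 1 and 6 h, 6.85-fold (5.63 to 8.40) higher at 1 h on the exonic scaling. Its exonic ratio was 1.20 at 1 h and 4.08 at 6 h. The sterol genes Cyp51 and Sqle were 5.89-fold (4.75 to 7.36) and 5.61-fold (3.90 to 8.32) higher in introns at 1 h, Peli1 4.03-fold (3.52 to 4.63), the transcription factor gene Nfil3 4.16-fold (2.89 to 6.14) and the synaptotagmin gene Syt4 4.46-fold (2.93 to 7.01). The exons of these 5 genes were also higher at 1 h, by less than their introns. The ratio of Cyp51 was 1.998 (1.81 to 2.21), just under the 2-fold rule, so it counted as late by a narrow margin. The other ratios were 1.51 for Sqle, 1.29 for Peli1, 1.75 for Nfil3 and 1.38 for Syt4. Homer1, a postsynaptic scaffold gene known to give a short activity-induced transcript, differed between its exons. Exons 1 to 6 together were 2.80-fold higher at 1 h (2.21 to 3.56), with 24, 132 and 131 reads at 0, 1 and 6 h in exon 1 and 22, 58 and 86 in exon 6, while exon 4 had 17, 23 and 35 and exon 5 had 5, 5 and 14. Exons 7 to 11 together, most of whose reads lay in exon 11, had a ratio of 1.04 at 1 h, with an interval on both sides of 1, and were 1.76-fold higher at 6 h (1.27 to 2.46).

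A hypothesis for the late genes is that unspliced RNA increases before exonic reads do. Of 276 late genes with enough intronic reads, 77 (27.9%) were at least 2-fold higher in introns at 1 h relative to other genes' introns, while the central 95% of random lists matched on intronic reads ended at 10.9%. Intronic reads of overlapping genes are argued against as the whole source, since among late genes that overlap no other the share was 28.8%. On the exonic scaling the share was 13.4%, where random lists ended at 4.71%. Among the late genes whose exonic interval at 1 h included 1, 203 had enough intronic reads; the share was 19.2% on the intronic scaling, where random lists ended at 11.3%, and 6.90% on the exonic scaling, where they ended at 4.93%. The single 0 h library entered both the choice of late genes and the intronic ratios, and the random lists were not chosen by it, so they do not give the share expected with no change. The hypothesis therefore stays open.

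Xist had 3191, 1983 and 2119 exonic reads, 1.80-fold lower at 1 h (1.71 to 1.91) and 1.59-fold lower at 6 h (1.51 to 1.68). The sum of 4 Y-linked genes was 1.32-fold (1.11 to 1.58) and 1.58-fold (1.33 to 1.88) higher. These genes moved apart: Ddx3y was 2.18-fold (1.46 to 3.31) higher at 1 h, and Jarid1d (Kdm5d) had a ratio of 0.983 (0.715 to 1.35). With 1 library per time, a response to KCl cannot be told apart here from a difference between the cultures in embryo sex. Reads in the 500 bp downstream of LOC627695 made up 5.58%, 3.99% and 3.62% of mapped reads at 0, 1 and 6 h.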
